A study of Mus musculus with 18 samples.

How the data were processed

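The values are messenger RNA levels of sorted cells from C57BL/6 mice, 9 populations with 2 libraries each. Per the labels, polyA RNA of sorted cells was reverse transcribed with indexed primers, the indexed samples were pooled, and the pooled cDNA was amplified linearly by in vitro transcription before sequencing. Per the submitters' processing notes, reads were aligned to mm9 with TopHat; the version of TopHat, the read counter, the gene annotation, any filter and the normalization tool are not given in the sources used here. The deposited table holds 1 signal value per RefSeq transcript and library, which the authors made by dividing read counts by 1 factor per library, and how that factor was found is not given in the sources used here. These signal values are called normalised reads in the results. Within each library 86.6% to 88.9% of the values above 0 were whole multiples of a single step, within a tolerance of 0.01 read, and that step was taken as the worth of 1 read. The remaining values were fractions of it, so the table does not hold whole counts and no method for raw counts was used. Dividing the summed values by the step gave 588858 to 1581367 reads in genes per library.

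The table had 20814 transcripts, of which 20372 (97.9%) were matched by their identifier to current gene symbols in a reference annotation, which was used for names alone. Of the transcripts, 235 have no symbol in the deposited data. The transcripts belonged to 16222 genes. For the 2967 genes with several transcripts, 829 of them with differing values, the transcript with the highest mean was used. Of all genes, 1281 genes share all their values with some other gene, and the values of near-identical copies, such as Hba-a1, Ly6c2, Reg3b, Serpina1a, Hspa1a and the H2 genes, are uncertain because it is unknown how reads that match several copies were shared out. Genes at 5.53 or more normalised reads (5 pseudocounts) in at least 2 libraries were tested, 12014 in all, 410 of them predicted genes without a name, which were counted and not named. Positions of genes are not given, because the table has none and the build of the reference differs from that of the alignment.

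Values were analysed as log2 of the value plus a pseudocount of 1.11, which is the median column total divided by 1e6, with the deposited scaling. A linear model with 1 factor of 9 populations (9 residual degrees of freedom) was fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a mean-variance trend. There were 12 comparisons: each of the 7 macrophage populations against the mean of the other 6, all 7 against monocytes and against neutrophils, monocytes against neutrophils, small against large intestine, and Kupffer cells against spleen. A gene was called at an adjusted p (limma, Benjamini-Hochberg, BH, within each comparison) under 0.05 with an absolute log2 fold change of at least 1, and "rose" or "fell" is used for called genes. All tests are two-sided. No group has more than 2 libraries, so no permutation of the libraries into other groups was run. Tables were prepared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. Within-experiment values compare a macrophage population with the other macrophage populations of its own experiment, and monocytes or neutrophils with the 3 macrophage populations of experiment 2.

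The comparisons, the test, the thresholds, the lists of genes, the rule for named genes and the main alternatives were chosen before the data were examined. For each macrophage comparison the rule names the 8 called genes with the highest log2 fold change whose libraries both lie above all libraries of the other 6 macrophage populations, the 4 lowest in the same way, up to 8 called members of the population's own marker list and up to 4 called transcription factors of a fixed list. For the other 5 comparisons it names the 10 highest and 10 lowest called genes without overlap between the sides and up to 8 called members of the marker lists of either side. Where a list is described, up to 4 called members with the largest change and up to 2 others may be named. The texts name those of these genes whose function is known with some certainty and whose call did not depend on the settings, or give the settings that end it; this choice among them was made after their values were seen. The 32 fixed lists were markers of microglia, of peritoneal, spleen red pulp, Kupffer, lung and intestinal macrophages, of monocytes and of neutrophils; shared macrophage genes; lineage and tissue transcription factors; MHC class II presentation, interferon-stimulated genes, inflammatory cytokines and chemokines, immediate early and heat shock genes, complement, lipid uptake and storage, cholesterol efflux and LXR, heme and iron handling, the TGF-beta pathway, the retinoic acid pathway and the cell cycle; and markers of B cells, T cells, dendritic cells, eosinophils and mast cells, erythroid cells, neurons and glia, hepatocytes, endothelium, lung epithelium, intestinal epithelium and mesothelium. The marker lists of the populations come from general knowledge that may include studies of these same samples, so the direction of these lists is not independent evidence. Each of the 31 lists with at least 3 tested members was tested in each comparison with limma's camera, at a preset correlation between genes of 0.01 and again with an estimated correlation, with BH adjustment over all 372 pairs of list and comparison. At the preset correlation 168 pairs passed, and with the estimated one 59, all in the same direction. Where a list is given without a count adjusted over the list alone, that count was the same as the one given. A list's median, mean and test differed in sign in 43 pairs, none of which passed.

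The model was tested on simulated data with added changes in 12 comparisons. It recovered 0% to 7.78% of genes changed 2-fold and 9.28% to 50.5% of genes changed 4-fold, the 4-fold share lowest for small against large intestine, with 0 to 7 unchanged genes called in a comparison. A true 2-fold change lies at the bound of a call itself, so low recovery there was set by the threshold. Each simulation changed 87 to 98 tested genes by each size, fewer than were called in most comparisons of the data. The adjustment over all genes was therefore stricter than in most comparisons, and the shares recovered may be too low for them. A gene that was not called can still differ by these amounts. The spread between replicates exceeded counting error, with a chi-square per degree of freedom of 3.65 in spleen to 13.5 in Kupffer cells. The alternatives chosen before the data were examined were a pseudocount of 0.277 or 4.43, no filter and a stricter filter, median-of-ratios scaling and quantile normalization, no mean-variance trend, only the populations compared, the replicate number as a block, the comparison within experiments, an estimated correlation, and leaving out each library in turn. A comparison that leaves out a library keeps a lone library of that population, which is assumed to vary like the others. Added after the data were seen were the sum of a gene's transcripts, voom weights, only genes of whole reads, equal library totals, a subtraction of 2 percent of the highest value among the other populations of the same experiment, and the numbered libraries without a block. Every column of values in the table belongs to 1 of the 18 libraries and was used.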

Results

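Messenger RNA was sequenced from sorted cells of C57BL/6 mice, with 9 populations and 2 libraries of each, 18 libraries in all. The 7 macrophage populations were microglia of the brain, macrophages of the peritoneal cavity, red pulp macrophages of the spleen, Kupffer cells of the liver, macrophages of the lung, and macrophages of the small intestine (ileum) and the large intestine (colon). Monocytes and neutrophils came from bone marrow. The question was how the gene expression of macrophages differs with the tissue in which they live, and how it differs from that of the other myeloid cells. The titles of the samples name 2 experiments: microglia, peritoneal macrophages and both intestinal populations belong to experiment 1, and spleen, Kupffer and lung macrophages, monocytes and neutrophils to experiment 2. Each population was made in 1 experiment, so a difference between populations of different experiments cannot be told apart from a difference between the experiments, and values within an experiment stand beside the pooled ones. The replicates are not stated to be separate animals, so every p measures only the spread between samples of the same population. In the main model this spread is pooled over all 9 populations.

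Levels are given in normalised reads, the deposited values, as mean ± SD (n = 2 libraries), and differences as log2 fold changes ± SE of the model. Reads in genes numbered 880850 and 918243 in microglia, 602012 and 809132 in peritoneal macrophages, 849746 and 588858 in spleen, 928622 and 738767 in Kupffer cells and 1367992 and 786571 in lung macrophages. They numbered 1518292 and 1370420 in small intestine macrophages, 785081 and 1581367 in large intestine macrophages, 953247 and 1108693 in monocytes and 1106991 and 719539 in neutrophils, each pair in order of replicate number. A gene with no read in a library has an upper limit of 3 reads there, which is 1.69 normalised reads in small intestine replicate 3 and 6.59 in neutrophil replicate 3. Such limits cover counting error only. Log2 fold changes were taken on the value plus a pseudocount of 1.11, which understates the change of genes at low levels, and no fold change is given where a population is listed at 0.

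Across 12014 tested genes, the Spearman correlation between the 2 libraries of a population ran from 0.867 to 0.949, and between libraries of different macrophage populations from 0.623 to 0.905. These correlations are across genes, which are not independent replicates. Small and large intestine macrophages were the closest pair of populations, with a mean of 0.893, followed by spleen and Kupffer macrophages with 0.824, and both of these pairs come from a single experiment. Microglia and neutrophils were the farthest apart, with 0.565. The first 3 principal components held 24.0%, 14.8% and 11.6% of the variance.

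**Figure D1:**
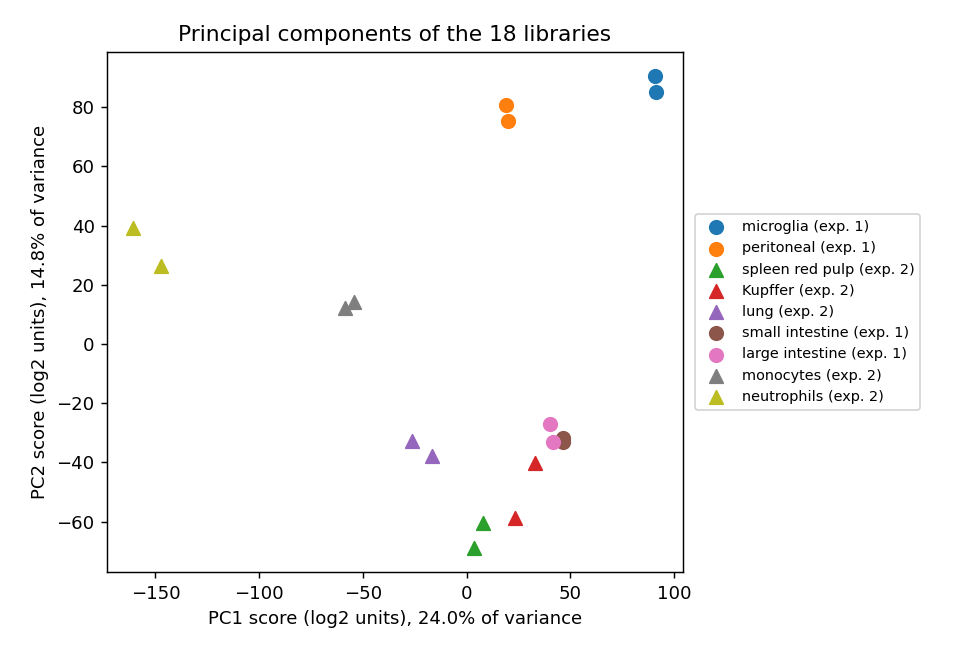
Scores of the 18 libraries on the first 2 principal components of the log2 values (log2 units), 1 point per library, with circles for experiment 1 and triangles for experiment 2. PC1 holds 24.0% and PC2 14.8% of the variance. The neutrophil libraries lie at one end of PC1 and the microglia libraries at the other, while the intestinal libraries lie close together, as do those of spleen and Kupffer replicate 1.

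**Figure D2:**
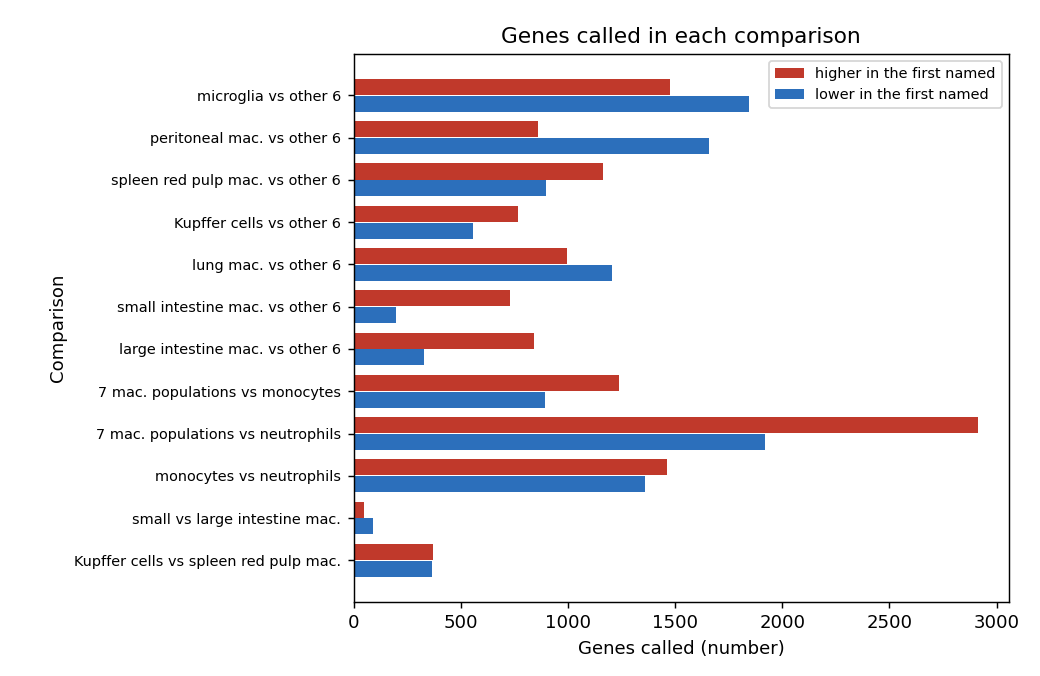
Number of genes called in each of the 12 comparisons (horizontal axis, number of genes; vertical axis, comparison), red for genes higher in the population named first and blue for genes lower in it. The counts run from 47 higher and 90 lower between the intestinal populations to 2911 higher and 1920 lower between the 7 macrophage populations and neutrophils.

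Microglia were compared with the mean of the other 6 macrophage populations. Sall1 and Sall3, zinc finger transcription factors, rose by log2 fold changes of 7.62 ± 0.44 and 7.62 ± 0.40, to 238 ± 6.97 and 250.1 ± 12.1 normalised reads. Tmem119, a membrane protein used to tell microglia from other macrophages of the brain, rose by 7.65 ± 0.67 to 6522 ± 348, and P2ry12, a receptor for ADP, rose by 6.51 ± 0.43 to 2412 ± 203. Crybb1, a crystallin gene, and Slc2a5, a fructose transporter, rose by 8.32 ± 0.67 and 8.18 ± 0.68. In the other direction, Cfp (properdin, of the alternative complement pathway) had a log2 fold change of -6.86 ± 0.23 and Ccnd2 (cyclin D2) of -6.73 ± 0.37, while Fgr, a Src family kinase, was listed at 0 in both microglia libraries and at 36.6 or more in every library of the other macrophages. Within experiment 1 the log2 fold changes of Sall1, Crybb1 and Cfp were 7.49, 7.66 and -6.62.

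Of the 20 microglia markers, 19 rose, 0 fell and 1 did not pass (limma's camera, adjusted p = 1.51e-24). Among them, Gpr34, a receptor for lysophosphatidylserine, rose by 6.41, and Siglech, a sialic acid binding lectin, by 6.89. Genes of lipid uptake and storage moved the other way: 0 rose, 12 fell and 6 did not pass, and 0 rose and 13 fell adjusted over the list alone (limma's camera, adjusted p = 1.71e-07). Fabp5, a fatty acid binding protein, had a log2 fold change of -4.39 ± 0.42, and Cd36, a scavenger receptor, and Pparg, a lipid-sensing nuclear receptor, were listed at 0 in both microglia libraries. Among genes of MHC class II presentation 0 rose, 7 fell and 3 did not pass (limma's camera, adjusted p = 9.85e-04, adjusted p = 0.223 with an estimated correlation), with log2 fold changes of -3.99 for Ciita, the transactivator of the class II genes, and -3.01 for Cd74, the invariant chain. In the cell cycle list 0 rose, 15 fell and 4 did not pass, and 0 rose and 16 fell adjusted over the list alone (limma's camera, adjusted p = 7.02e-07, adjusted p = 0.114 with an estimated correlation), and Ube2c, a ubiquitin-conjugating enzyme of mitosis, had a log2 fold change of -3.81. In the TGF-beta pathway 6 rose, 1 fell and 6 did not pass (limma's camera, adjusted p = 0.0129, adjusted p = 0.0791 with an estimated correlation), with the receptor Tgfbr1 at 3.78 and the inhibitor Smad7 at 3.13, and Tgfbi, an induced matrix protein, at -3.34. Of neuron and glia markers 0 rose, 1 fell and 3 did not pass (limma's camera, adjusted p = 0.990), and the member that fell, Slc1a2, a glutamate transporter, had a log2 fold change of -1.50 (limma, BH, adjusted p = 0.491 within experiment 1, 0.0510 without monocytes replicate 1, 0.0510 without monocytes replicate 2, 0.166 without microglia replicate 1, 0.175 without microglia replicate 2, 0.0535 without large intestine macrophages replicate 3, 0.0526 without small intestine macrophages replicate 4). For erythroid markers 0 rose, 1 fell and 8 did not pass (limma's camera, adjusted p = 0.855). The lineage and tissue transcription factors went both ways: 9 rose, 13 fell and 12 did not pass, and 9 rose and 14 fell adjusted over the list alone (limma's camera, adjusted p = 0.433). Within experiment 1, 19 of the microglia markers rose and 0 fell (limma's camera, adjusted p = 3.80e-23). Lipid genes had 1 rising and 10 falling members within the experiment (limma's camera, adjusted p = 5.26e-05). Of the MHC class II genes, 0 rose and 7 fell there (limma's camera, adjusted p = 2.05e-05). Cell cycle genes had 0 rising and 13 falling members within the experiment (limma's camera, adjusted p = 1.40e-06). Of the TGF-beta genes, 5 rose and 3 fell there (limma's camera, adjusted p = 0.0957). Erythroid markers had 5 rising and 1 falling members within the experiment (limma's camera, adjusted p = 0.0168). Of the transcription factors, 8 rose and 12 fell there (limma's camera, adjusted p = 0.717).

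In all, 1475 genes rose and 1843 fell in microglia, and 1288 rose and 1818 fell within experiment 1, with 2454 genes called in the same direction both ways. Every gene given a log2 fold change above had an adjusted p (limma, BH) of at most 0.0383 for Slc1a2. The count of 3318 genes fell to 2129 without microglia replicate 1 and to 1929 without replicate 2.

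Peritoneal macrophages were compared with the other 6 populations in the same way. Alox15, a lipoxygenase of arachidonic and linoleic acid, rose by 10.81 ± 0.96 to 6347 ± 786 normalised reads, the highest log2 fold change in this comparison. Prg4, the lubricant proteoglycan 4, rose by 9.33 ± 0.59, Selp (P-selectin) by 8.26 ± 0.59, Serpinb2, a serine protease inhibitor, by 8.25 ± 0.72 and Padi4, a peptidylarginine deiminase, by 8.24 ± 0.50. The transcription factor gene Gata6 rose by 6.33 ± 0.56 to 171 ± 31.0, and Klf2 by 3.48 ± 0.26. Mgll, a monoacylglycerol lipase, and Asb2, a subunit of a ubiquitin ligase, had log2 fold changes of -6.32 ± 0.30 and -6.24 ± 0.51, and Acvrl1, a receptor of the TGF-beta family, was listed at 0 in both peritoneal libraries and at 61.1 or more in all other macrophage libraries. Within experiment 1 the log2 fold changes of Alox15, Gata6 and Mgll were 10.43, 5.88 and -5.12.

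Of the 20 peritoneal macrophage markers, 20 rose, 0 fell and 0 did not pass (limma's camera, adjusted p = 8.71e-31). They include Tgfb2, a ligand of the TGF-beta family, at 7.72, and Ltbp1, which binds latent TGF-beta, at 7.67. In the retinoic acid pathway 6 rose, 1 fell and 4 did not pass (limma's camera, adjusted p = 4.97e-04). The receptors Rarg and Rarb rose by 4.19 and 3.07 and Cyp26a1, which degrades retinoic acid, by 3.98, whereas Tgm2, a transglutaminase, had -2.97. For MHC class II presentation 0 rose, 10 fell and 0 did not pass (limma's camera, adjusted p = 2.33e-10), with H2-DMb1, a chaperone of peptide loading, at -3.12. For inflammatory cytokines and chemokines 0 rose, 11 fell and 5 did not pass, and 0 rose and 12 fell adjusted over the list alone (limma's camera, adjusted p = 2.37e-05, adjusted p = 0.143 with an estimated correlation), with the chemokine gene Cxcl10 at -4.73 and the interleukin gene Il1b at -4.68. For immediate early and heat shock genes 0 rose, 9 fell and 7 did not pass (limma's camera, adjusted p = 4.68e-05, adjusted p = 0.308 with an estimated correlation), with the AP-1 genes Fos and Jun at -3.77 and -3.33. The mesothelium markers had fewer than 3 tested members and were not tested. Within experiment 1, 19 of the peritoneal macrophage markers rose and 0 fell (limma's camera, adjusted p = 1.76e-29). Retinoic acid genes had 6 rising and 1 falling members within the experiment (limma's camera, adjusted p = 1.13e-05). Of the MHC class II genes, 0 rose and 10 fell there (limma's camera, adjusted p = 6.96e-13). Cytokines and chemokines had 0 rising and 12 falling members within the experiment (limma's camera, adjusted p = 3.17e-06). Of the immediate early and heat shock genes, 0 rose and 12 fell there (limma's camera, adjusted p = 1.32e-07).

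A total of 861 genes rose and 1656 fell in peritoneal macrophages, against 843 and 1727 within experiment 1 and 1851 called in the same direction both ways. The adjusted p (limma, BH) of the genes named with a log2 fold change was at most 4.76e-05 for Rarb. The count of 2517 became 1348 without peritoneal replicate 1, and the share of called genes that were higher moved from 34.2% to 47.2% with quantile normalization, 45.6% with equal library totals and 46.1% with voom weights.

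Red pulp macrophages of the spleen were higher than the mean of the other 6 populations in genes of heme breakdown and iron export, in part shared with Kupffer cells. Spic, a transcription factor needed for red pulp macrophages, rose by 6.94 ± 0.53 to 671 ± 29.3 normalised reads, Vcam1, an adhesion molecule, by 6.50 ± 0.38 to 1377 ± 274, and Itgad, the integrin alpha D, by 7.32 ± 0.56. Hmox1, the heme oxygenase that breaks down heme, rose by 5.14 ± 0.28 to 4297 ± 421, and Slc40a1 (ferroportin, the iron exporter) by 4.66 ± 0.46. Hs3st2, a sulfotransferase of heparan sulfate, and Gfra2, a receptor for neurturin, rose by 7.12 ± 0.46 and 6.65 ± 0.64. Plxdc2, a membrane protein, Fcgr2b, the inhibitory Fc receptor, and Ccl9, a chemokine, had log2 fold changes of -5.60 ± 0.54, -4.98 ± 0.48 and -4.90 ± 0.49. Within experiment 2 Spic, Hmox1 and Plxdc2 had 4.98, 3.73 and -3.13.

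Of the spleen red pulp markers, 15 rose, 0 fell and 1 did not pass (limma's camera, adjusted p = 8.92e-24). For heme and iron handling 9 rose, 1 fell and 6 did not pass, and 10 rose and 1 fell adjusted over the list alone (limma's camera, adjusted p = 2.66e-06), with Cd163, the receptor for hemoglobin and haptoglobin, at 4.30, and Nfe2l2, a transcription factor of the oxidative stress response, at -3.12. For interferon-stimulated genes 8 rose, 0 fell and 10 did not pass, and 9 rose and 0 fell adjusted over the list alone (limma's camera, adjusted p = 1.58e-05, adjusted p = 0.0589 with an estimated correlation), with Rsad2, an antiviral enzyme, at 2.70 and Irf7, a transcription factor, at 2.45. For the TGF-beta pathway 0 rose, 5 fell and 8 did not pass, and 0 rose and 7 fell adjusted over the list alone (limma's camera, adjusted p = 0.00109), with Smad7 at -2.44 (limma, BH, adjusted p = 0.137 without spleen red pulp macrophages replicate 1). Markers of other blood cells also stood higher in the spleen libraries. For erythroid markers 9 rose, 0 fell and 0 did not pass (limma's camera, adjusted p = 5.08e-11, adjusted p = 0.0546 with an estimated correlation), with Slc4a1, the anion exchanger of red cells, at 7.24 and 489 ± 71.4 normalised reads, and Klf1, an erythroid transcription factor, at 4.77. For neutrophil markers 14 rose, 0 fell and 4 did not pass (limma's camera, adjusted p = 9.52e-10, adjusted p = 0.121 with an estimated correlation), with Ltf (lactoferrin) at 5.61 and 0.95 within experiment 2, where it did not pass (limma, BH, adjusted p = 0.405), and for B cell markers 5 rose, 0 fell and 3 did not pass (limma's camera, adjusted p = 0.00432, adjusted p = 0.347 with an estimated correlation). Within experiment 2, 13 of the spleen red pulp macrophage markers rose and 0 fell (limma's camera, adjusted p = 3.85e-18). Heme and iron genes had 7 rising and 2 falling members within the experiment (limma's camera, adjusted p = 0.00136). Of the interferon-stimulated genes, 4 rose and 0 fell there (limma's camera, adjusted p = 1.54e-04). TGF-beta genes had 0 rising and 2 falling members within the experiment (limma's camera, adjusted p = 0.121). Of the erythroid markers, 9 rose and 0 fell there (limma's camera, adjusted p = 2.15e-09). Neutrophil markers had 0 rising and 0 falling members within the experiment (limma's camera, adjusted p = 0.0374). Of the B cell markers, 2 rose and 0 fell there (limma's camera, adjusted p = 0.115).

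In total 1162 genes rose and 897 fell in spleen red pulp macrophages, but 690 and 585 within experiment 2, where 880 were called in the same direction both ways. The highest adjusted p (limma, BH) among the genes given with a log2 fold change was 0.00214 for Smad7. The count of 2059 fell to 1133 without spleen replicate 1 and 844 without replicate 2, and with voom weights the share of called genes that were higher moved from 56.4% to 72.8%.

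Kupffer cells expressed markers of liver macrophages together with interferon-stimulated genes. Clec4f, a C-type lectin of Kupffer cells, rose by 11.31 ± 0.86 to 7933 ± 2353 normalised reads, against 71.3 in spleen, 66.2 in monocytes and 85.7 in neutrophils. Cd5l, a secreted scavenger protein, rose by 7.92 ± 0.70, Vsig4, a receptor for complement C3 fragments, by 6.65 ± 0.59, Cd207, a lectin also known from Langerhans cells, by 6.54 ± 0.54 and Folr2, a folate receptor, by 6.84 ± 0.76. The transcription regulators Id3 and Nr1h3 (the liver X receptor alpha) rose by 5.64 ± 0.55 and 5.15 ± 0.50. Slco2b1, an organic anion transporter, and Sort1 (sortilin) had log2 fold changes of -5.22 ± 0.40 and -4.44 ± 0.27. Within experiment 2 Clec4f had 8.37, Nr1h3 2.02 and Slco2b1 -5.20.

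Of the 18 Kupffer cell markers, 18 rose, 0 fell and 0 did not pass (limma's camera, adjusted p = 5.83e-33). For interferon-stimulated genes 18 rose, 0 fell and 0 did not pass (limma's camera, adjusted p = 3.20e-22), with Irf7 at 3.25, Rsad2 at 3.72 and Mx1, a GTPase that restricts viruses, at 3.57. For complement 9 rose, 1 fell and 4 did not pass, and 12 rose and 2 fell adjusted over the list alone (limma's camera, adjusted p = 2.64e-07), with C6, a part of the membrane attack complex, at 5.31. For heme and iron handling 7 rose, 0 fell and 9 did not pass, and 9 rose and 0 fell adjusted over the list alone (limma's camera, adjusted p = 1.66e-07), with Slc40a1 at 4.88, Cd163 at 4.68 and Hpx (hemopexin, which binds heme) at 5.55. Hpx, like the hepatocyte markers Alb and Apoa2, was higher in Kupffer cells than in each other macrophage population. Whether hepatocyte RNA carried into the sort adds to its level was not tested. For cholesterol efflux and LXR 5 rose, 0 fell and 7 did not pass (limma's camera, adjusted p = 4.18e-05), with Apoc1, an apolipoprotein, at 6.08 and Pltp, which transfers phospholipids, at 2.73. For the lineage and tissue transcription factors 12 rose, 7 fell and 15 did not pass, and 13 rose and 8 fell adjusted over the list alone (limma's camera, adjusted p = 0.0115, adjusted p = 0.151 with an estimated correlation, adjusted p = 0.175 without Kupffer cells replicate 1). Transcripts typical of other cells of the liver moved with these groups. For hepatocyte markers 8 rose, 0 fell and 0 did not pass (limma's camera, adjusted p = 6.10e-12), with Alb (albumin) at 7.13 and 638 ± 666 normalised reads, and Apoa2, an apolipoprotein, at 5.52. For endothelium markers 7 rose, 0 fell and 2 did not pass (limma's camera, adjusted p = 1.06e-09), with Stab2, a scavenger receptor of liver sinusoids, at 6.10 and Cdh5 (VE-cadherin, also among the 18 Kupffer markers) at 5.38. For neutrophil markers 8 rose, 0 fell and 10 did not pass (limma's camera, adjusted p = 0.00131, adjusted p = 0.372 with an estimated correlation, adjusted p = 0.644 without Kupffer cells replicate 1) and for erythroid markers 5 rose, 0 fell and 4 did not pass (limma's camera, adjusted p = 0.00595, adjusted p = 0.365 with an estimated correlation, adjusted p = 0.0514 without Kupffer cells replicate 1).

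Within experiment 2, 18 of the Kupffer cell markers rose and 0 fell (limma's camera, adjusted p = 2.05e-23). Interferon-stimulated genes had 18 rising and 0 falling members within the experiment (limma's camera, adjusted p = 9.67e-22). Of the complement genes, 10 rose and 0 fell there (limma's camera, adjusted p = 1.09e-12). Heme and iron genes had 7 rising and 2 falling members within the experiment (limma's camera, adjusted p = 0.0175). Of the cholesterol and LXR genes, 5 rose and 1 fell there (limma's camera, adjusted p = 0.00195). Transcription factors had 8 rising and 4 falling members within the experiment (limma's camera, adjusted p = 0.0250). Of the hepatocyte markers, 8 rose and 0 fell there (limma's camera, adjusted p = 3.08e-12). Endothelium markers had 6 rising and 0 falling members within the experiment (limma's camera, adjusted p = 4.48e-06). Of the neutrophil markers, 0 rose and 2 fell there (limma's camera, adjusted p = 1.35e-04). Erythroid markers had 0 rising and 1 falling members within the experiment (limma's camera, adjusted p = 0.448). Across all genes 765 rose and 555 fell in Kupffer cells, with 658 and 547 within experiment 2 and 642 in both in the same direction. For the Kupffer genes given a log2 fold change, the adjusted p (limma, BH) was at most 6.53e-04 for Mx1. The count of 1320 fell to 837 without Kupffer replicate 2, and with voom weights the share of called genes that were higher moved from 58.0% to 73.4%.

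Lung macrophages combined genes of lipid handling with a low expression of complement C1q and of the transcription factor gene Maf. Chil3, a chitinase-like protein, rose by 9.44 ± 0.72 to 6372 ± 2404 normalised reads, Krt79, a keratin, by 9.03 ± 0.61, Atp6v0d2, a subunit of the vacuolar proton pump, by 8.39 ± 0.70 and Cidec, a protein of lipid droplets, by 8.17 ± 0.62. Ctsk (cathepsin K) rose by 7.27 ± 0.68, Car4, a carbonic anhydrase, by 7.16 ± 0.63 and the transcription factor gene Runx2 by 4.34 ± 0.59. Maf had a log2 fold change of -6.09 ± 0.47. Pdlim4, a cytoskeletal adaptor, and C3ar1, the receptor for complement C3a, had -6.36 ± 0.24 and -6.17 ± 0.45. Within experiment 2 Chil3 had 8.38, Krt79 8.70 and Maf -6.68.

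Of the lung macrophage markers, 24 rose, 0 fell and 0 did not pass (limma's camera, adjusted p = 3.35e-32). For lipid uptake and storage 13 rose, 1 fell and 4 did not pass, and 15 rose and 1 fell adjusted over the list alone (limma's camera, adjusted p = 1.78e-12), with Olr1, a receptor for oxidised lipoprotein, at 6.56 and Fabp1, a fatty acid binding protein, at 6.07. For complement 2 rose, 11 fell and 1 did not pass (limma's camera, adjusted p = 3.55e-07), with the C1q genes C1qa, C1qb and C1qc at -6.76, -7.53 and -6.02. For interferon-stimulated genes 0 rose, 16 fell and 2 did not pass, and 0 rose and 18 fell adjusted over the list alone (limma's camera, adjusted p = 1.19e-12), with Rsad2 at -4.48 and Rtp4 at -3.37. Markers of other lung and blood cells were measured beside these. For lung epithelium markers 6 rose, 0 fell and 0 did not pass (limma's camera, adjusted p = 1.28e-09), with the surfactant proteins Sftpc, Sftpa1 and Sftpb at 8.58, 6.28 and 6.28. For T cell markers 6 rose, 0 fell and 2 did not pass (limma's camera, adjusted p = 7.29e-04, adjusted p = 0.152 with an estimated correlation), with Cd2, an adhesion molecule of T cells, at 6.83 and 665 ± 7.70 normalised reads. For neutrophil markers 12 rose, 1 fell and 5 did not pass, and 13 rose and 2 fell adjusted over the list alone (limma's camera, adjusted p = 7.74e-08, adjusted p = 0.166 with an estimated correlation), and for eosinophil and mast cell markers 0 rose, 0 fell and 3 did not pass (limma's camera, adjusted p = 0.685). Within experiment 2, 22 of the lung macrophage markers rose and 0 fell (limma's camera, adjusted p = 8.49e-26). Lipid genes had 12 rising and 1 falling members within the experiment (limma's camera, adjusted p = 4.54e-09). Of the complement genes, 1 rose and 10 fell there (limma's camera, adjusted p = 1.64e-08). Interferon-stimulated genes had 0 rising and 18 falling members within the experiment (limma's camera, adjusted p = 5.65e-20). Of the lung epithelium markers, 6 rose and 0 fell there (limma's camera, adjusted p = 8.30e-09). T cell markers had 2 rising and 0 falling members within the experiment (limma's camera, adjusted p = 0.0104). Of the neutrophil markers, 2 rose and 1 fell there (limma's camera, adjusted p = 0.187).

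Altogether 997 genes rose and 1204 fell in lung macrophages, and 949 and 1221 within experiment 2, with 1413 called in the same direction both ways. The lung genes given a log2 fold change had an adjusted p (limma, BH) of at most 2.33e-05 for Runx2. The count of 2201 fell to 1146 without lung replicate 2.

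**Figure D3:**
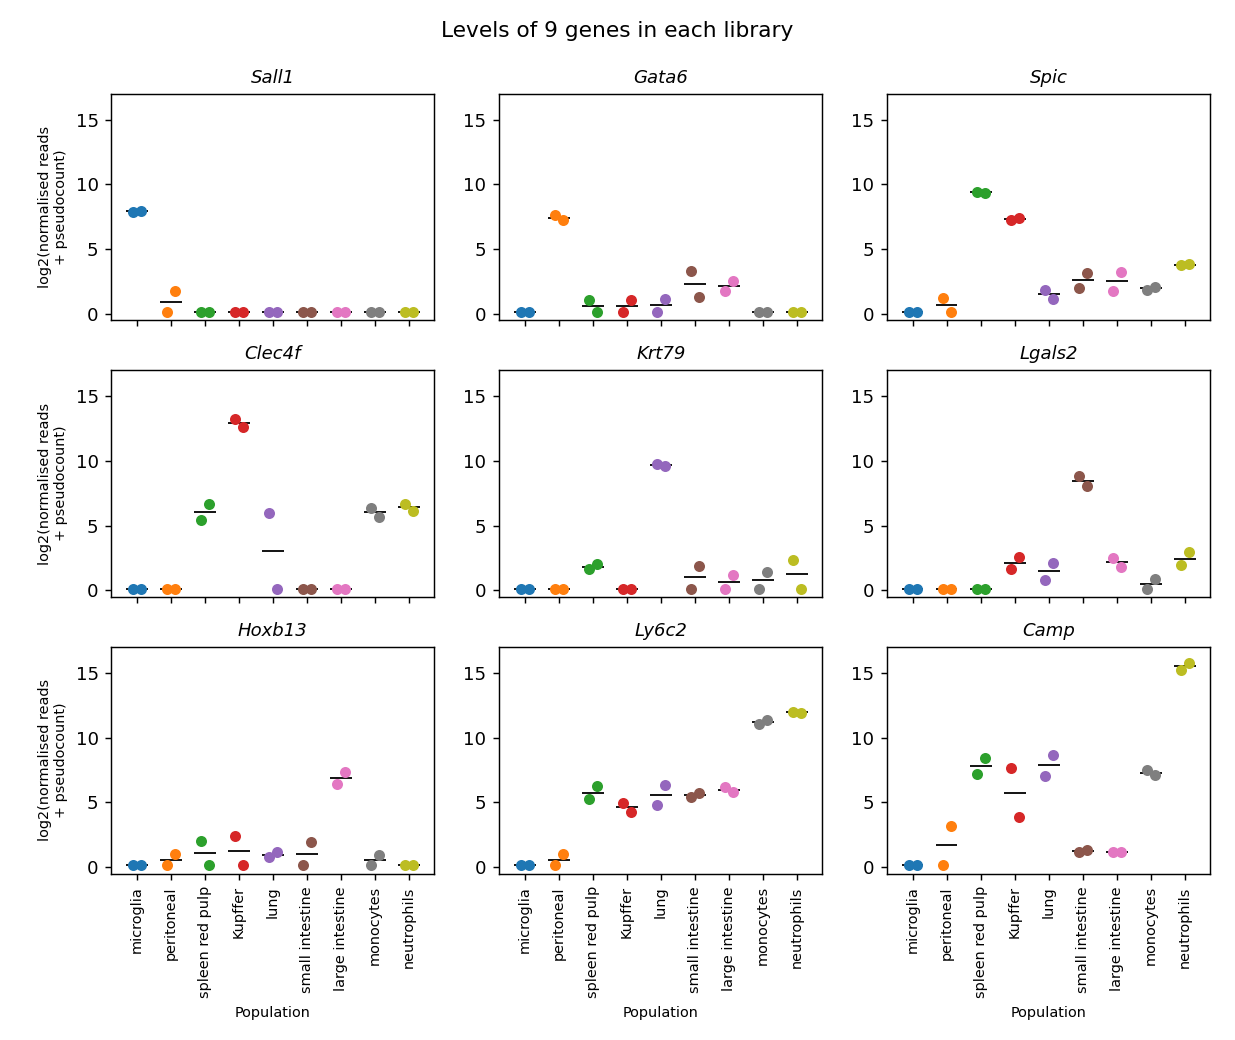
Levels of 9 genes, 1 panel each, as log2(normalised reads + 1.11) (vertical axis), by population (horizontal axis). Points are libraries and lines their means. Sall1 lies highest in microglia, Gata6 in peritoneal macrophages, Spic in spleen, Clec4f in Kupffer cells, Krt79 in lung, Lgals2 in small intestine and Hoxb13 in large intestine macrophages, and Ly6c2 and Camp in the bone marrow cells. Whether epithelium adds to Lgals2 or Hoxb13 was not tested.

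**Figure D4:**
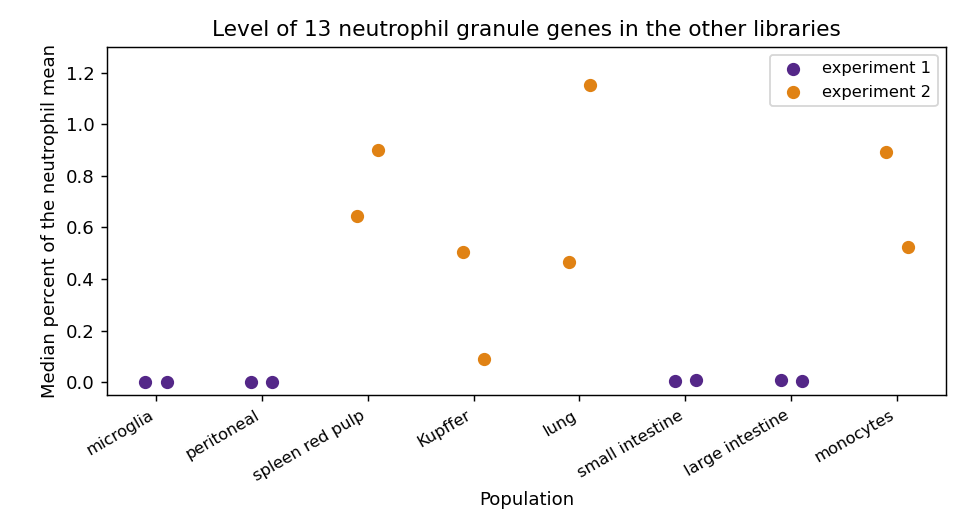
Median level of 13 neutrophil granule genes in each library other than neutrophils, as a percent of the neutrophil mean (vertical axis), by population (horizontal axis), 1 point per library, orange for experiment 2 and purple for experiment 1. The libraries of experiment 1 lie at 0.0103% or less and those of experiment 2 between 0.0922% (Kupffer replicate 2) and 1.15% (lung replicate 2).

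Genes of MHC class II presentation were higher in small intestine macrophages than in the mean of the other 6 populations, and they were in large intestine macrophages as well. Lgals2, a galectin, rose by 7.41 ± 0.55 to 360.0 ± 134 normalised reads, Apol7c, of the apolipoprotein L family, by 6.24 ± 0.54 to 950.2 ± 17.4, Dnase1l3, a secreted DNase, by 5.09 ± 0.42 and Mmp9, a matrix metalloproteinase, by 4.44 ± 0.35. The anti-inflammatory cytokine gene Il10 rose by 2.73 ± 0.41. The MHC class II genes H2-Eb1, H2-Aa and H2-Ab1 rose by 4.49 ± 0.32, 3.90 ± 0.33 and 3.62 ± 0.35, with H2-Eb1 at 9161 ± 2686 normalised reads. St3gal5, a sialyltransferase of ganglioside synthesis, and Ctsd (cathepsin D) had log2 fold changes of -4.70 ± 0.32 and -3.18 ± 0.25. Within experiment 1 Lgals2 had 7.63, H2-Eb1 4.20 and St3gal5 -5.24.

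Of the intestinal macrophage markers, 11 rose, 0 fell and 4 did not pass, and 14 rose and 0 fell adjusted over the list alone (limma's camera, adjusted p = 4.11e-17). For MHC class II presentation 9 rose, 0 fell and 1 did not pass, and 10 rose and 0 fell adjusted over the list alone (limma's camera, adjusted p = 1.61e-16). For immediate early and heat shock genes 10 rose, 0 fell and 6 did not pass, and 12 rose and 0 fell adjusted over the list alone (limma's camera, adjusted p = 9.98e-09, adjusted p = 0.176 with an estimated correlation), with Hspa1a, a chaperone with a near-identical copy, at 3.02 (limma, BH, adjusted p = 0.0992 without small intestine macrophages replicate 4). For inflammatory cytokines and chemokines 9 rose, 1 fell and 6 did not pass, and 10 rose and 1 fell adjusted over the list alone (limma's camera, adjusted p = 2.23e-06, adjusted p = 0.104 with an estimated correlation), with Ptgs2, the inducible cyclooxygenase, at 3.36 and the chemokine gene Ccl3 at 2.69. For monocyte markers 5 rose, 1 fell and 8 did not pass, and 6 rose and 1 fell adjusted over the list alone (limma's camera, adjusted p = 0.00663, adjusted p = 0.107 with an estimated correlation, adjusted p = 0.0713 without small intestine macrophages replicate 4), with Ccr2, a chemokine receptor, at 3.90 and Plac8 at 2.94. For dendritic cell markers 2 rose, 0 fell and 3 did not pass, and 3 rose and 0 fell adjusted over the list alone (limma's camera, adjusted p = 0.0108, adjusted p = 0.176 with an estimated correlation, adjusted p = 0.0706 without small intestine macrophages replicate 4), with the chemokine receptor gene Xcr1 at 2.85. With the replicate number as a block the calls of Hspa1a, Ptgs2, Ccl3, Ccr2, Plac8 and Xcr1 ended (limma, BH, adjusted p = 0.0576 for Ccr2 to 0.201 for Ptgs2). Transcripts of the gut epithelium were present in the same libraries: 10 rose, 0 fell and 0 did not pass (limma's camera, adjusted p = 1.75e-12), with the antimicrobial lectins Reg3g and Reg3b at 6.80 and 5.56. Within experiment 1, 12 of the intestinal macrophage markers rose and 0 fell (limma's camera, adjusted p = 3.44e-17). MHC class II genes had 8 rising and 0 falling members within the experiment (limma's camera, adjusted p = 1.33e-15). Of the immediate early and heat shock genes, 6 rose and 0 fell there (limma's camera, adjusted p = 2.46e-06). Cytokines and chemokines had 7 rising and 0 falling members within the experiment (limma's camera, adjusted p = 1.94e-06). Of the monocyte markers, 5 rose and 1 fell there (limma's camera, adjusted p = 0.00287). Dendritic cell markers had 3 rising and 0 falling members within the experiment (limma's camera, adjusted p = 0.00517). Of the intestinal epithelium markers, 10 rose and 0 fell there (limma's camera, adjusted p = 2.44e-09).

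Among all tested genes 729 rose and 199 fell in small intestine macrophages, and 750 and 218 within experiment 1, of which 584 were called in the same direction both ways. For the named small intestine genes the adjusted p (limma, BH) was at most 0.00108 for Hspa1a. The count of 928 fell to 340 without small intestine replicate 3 and 370 without replicate 4 and came to 1528 with voom weights and 117 with the replicate number as a block, and the share of higher genes moved from 78.6% to 65.9% with quantile normalization.

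Large intestine macrophages also had higher MHC class II genes than the mean of the other 6 populations. H2-Eb1, H2-Aa and H2-Ab1 rose by 4.53 ± 0.32, 4.17 ± 0.33 and 4.10 ± 0.35, and Ciita by 3.88 ± 0.40. The T cell coreceptor gene Cd4, which some macrophages express, rose by 5.04 ± 0.78, Dnase1l3 by 4.29 ± 0.42, the transcription factor gene Runx3 by 4.11 ± 0.44 and Mmp13, a collagenase, by 4.02 ± 0.65. Oit1 and Lypd8, genes of colon epithelium, rose by 6.50 ± 0.81 and 6.46 ± 0.75, Car1, a carbonic anhydrase, by 6.30 ± 0.77 and Hoxb13, a posterior homeobox gene, by 6.03 ± 0.63 to 122 ± 52.3 normalised reads. Mertk, a receptor for dying cells, and Fabp4, a fatty acid binding protein, had log2 fold changes of -3.22 ± 0.27 and -3.22 ± 0.52. Within experiment 1 H2-Eb1 had 4.24, Hoxb13 6.29 and Mertk -2.51.

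Of the intestinal macrophage markers, 9 rose, 0 fell and 6 did not pass, and 12 rose and 0 fell adjusted over the list alone (limma's camera, adjusted p = 3.87e-09). For MHC class II presentation 10 rose, 0 fell and 0 did not pass (limma's camera, adjusted p = 9.36e-17). For monocyte markers 6 rose, 0 fell and 8 did not pass, and 7 rose and 0 fell adjusted over the list alone (limma's camera, adjusted p = 5.02e-05), with Ccr2, the chemokine receptor that draws monocytes into tissue, at 4.37, S100a4, a calcium binding protein, at 4.29 and F13a1, a coagulation factor chain, at 3.13. For immediate early and heat shock genes 4 rose, 0 fell and 12 did not pass, and 6 rose and 0 fell adjusted over the list alone (limma's camera, adjusted p = 3.91e-04, adjusted p = 0.372 with an estimated correlation, adjusted p = 0.231 without large intestine macrophages replicate 2). Epithelial transcripts moved with these groups: 8 rose, 0 fell and 2 did not pass, and 9 rose and 0 fell adjusted over the list alone (limma's camera, adjusted p = 4.00e-10, adjusted p = 0.0518 with an estimated correlation), with the keratins Krt8 and Krt18 at 5.65 and 4.79 and Vil1 (villin) at 4.68. Within experiment 1, 11 of the intestinal macrophage markers rose and 0 fell (limma's camera, adjusted p = 6.53e-10). MHC class II genes had 9 rising and 0 falling members within the experiment (limma's camera, adjusted p = 6.86e-17). Of the monocyte markers, 8 rose and 0 fell there (limma's camera, adjusted p = 9.46e-06). Immediate early and heat shock genes had 0 rising and 0 falling members within the experiment (limma's camera, adjusted p = 0.0175). Of the intestinal epithelium markers, 7 rose and 0 fell there (limma's camera, adjusted p = 9.05e-07).

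The large intestine comparison called 842 genes higher and 329 lower, with 853 and 254 within experiment 1 and 750 in the same direction both ways. Its named genes had an adjusted p (limma, BH) of at most 0.00106 for F13a1. The count of 1171 fell to 503 without large intestine replicate 2 and 612 without replicate 3, and the share of higher genes moved from 71.9% to 61.3% with quantile normalization.

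Genes higher in 1 macrophage population than in each of the other 6 were counted from the pairwise contrasts of the same model (limma, BH within each contrast). There were 264 such genes for microglia, 171 for lung, 146 for peritoneal, 87 for spleen, 66 for Kupffer, 54 for large intestine and 31 for small intestine macrophages, 819 in all. Within experiments, where fewer populations must be exceeded, there were 535 for lung, 454 for microglia, 295 for peritoneal, 207 for Kupffer, 198 for spleen, 73 for large intestine and 40 for small intestine macrophages, 1802 in all, and the order differed.

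The 7 macrophage populations together were higher than bone marrow monocytes in shared macrophage genes, and lower in monocyte markers and cell cycle genes. Mertk, a receptor for dying cells, rose in macrophages by 5.05 ± 0.27, the complement genes C1qa and C1qb by 4.70 ± 0.34 and 5.03 ± 0.31, Cd81, a tetraspanin, by 7.23 ± 0.26 and Abca1, a cholesterol exporter, by 4.54 ± 0.59. Genes higher in monocytes included Ly6c2, a surface antigen of classical monocytes, with a log2 fold change of -7.18 ± 0.36, Ccr2 with -4.98 ± 0.37 and F13a1 with -6.11 ± 0.57. Against the 3 macrophage populations of experiment 2 alone, C1qb had 3.45, Mertk 6.21 and Ly6c2 -5.90.

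Of the shared macrophage genes, 23 rose, 0 fell and 6 did not pass (limma's camera, adjusted p = 3.85e-15). For monocyte markers 0 rose, 13 fell and 1 did not pass, and 1 rose and 13 fell adjusted over the list alone (limma's camera, adjusted p = 8.59e-19), with Plac8 at -5.63 and S100a4 at -5.15. For the cell cycle 0 rose, 16 fell and 3 did not pass, and 0 rose and 18 fell adjusted over the list alone (limma's camera, adjusted p = 2.95e-14), with Ccnb2 (cyclin B2) at -4.19, Cdc20, an activator of the anaphase-promoting complex, at -3.75 and Birc5 (survivin) at -3.25. For cholesterol efflux and LXR 7 rose, 0 fell and 5 did not pass (limma's camera, adjusted p = 1.42e-04), and for MHC class II presentation 7 rose, 0 fell and 3 did not pass (limma's camera, adjusted p = 2.04e-06, adjusted p = 0.103 with an estimated correlation), with H2-Eb1 at 3.47. For complement 9 rose, 1 fell and 4 did not pass (limma's camera, adjusted p = 1.45e-04, adjusted p = 0.0953 with an estimated correlation). Within experiment 2, 20 of the shared macrophage genes rose and 2 fell (limma's camera, adjusted p = 3.37e-13). Monocyte markers had 0 rising and 13 falling members within the experiment (limma's camera, adjusted p = 3.07e-17). Of the cell cycle genes, 0 rose and 14 fell there (limma's camera, adjusted p = 5.91e-10). Cholesterol and LXR genes had 9 rising and 0 falling members within the experiment (limma's camera, adjusted p = 8.29e-07). Of the MHC class II genes, 6 rose and 0 fell there (limma's camera, adjusted p = 2.10e-04). Complement genes had 10 rising and 3 falling members within the experiment (limma's camera, adjusted p = 5.38e-04).

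Against monocytes 1238 genes rose and 891 fell in macrophages, with 1454 and 886 within experiment 2 and 1565 in the same direction both ways, and the named genes had an adjusted p (limma, BH) of at most 4.88e-04 for Birc5. The count of 2129 fell to 1095 without monocyte replicate 1 and 904 without replicate 2.

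Macrophages and neutrophils were compared next, and the granule genes of neutrophils were far lower in macrophages. Lgmn (legumain, a lysosomal protease) rose by 5.53 ± 0.21, Fcgr1, the high-affinity Fc receptor for IgG, by 4.51 ± 0.28, Adgre1, the F4/80 antigen, by 4.41 ± 0.25 and Mertk by 4.59 ± 0.27. Camp, the cathelicidin of neutrophil granules, had a log2 fold change of -11.83 ± 0.71 and stood at 46901 ± 11738 normalised reads in neutrophils, Ltf (lactoferrin) had -11.44 ± 0.56, Lcn2 (lipocalin 2) -11.20 ± 0.52, and the calcium binding proteins S100a8 and S100a9 had -10.86 ± 0.59 and -11.59 ± 0.59. With the macrophages of experiment 2 alone, Lgmn had 4.81 and Camp -8.36. Of the neutrophil markers, 0 rose, 17 fell and 1 did not pass (limma's camera, adjusted p = 2.27e-18). For the shared macrophage genes 20 rose, 5 fell and 4 did not pass (limma's camera, adjusted p = 1.23e-05, adjusted p = 0.165 with an estimated correlation). Within experiment 2, 0 of the neutrophil markers rose and 17 fell (limma's camera, adjusted p = 2.83e-16). Shared macrophage genes had 21 rising and 5 falling members within the experiment (limma's camera, adjusted p = 3.92e-06). The comparison with neutrophils called 2911 genes higher and 1920 lower in macrophages, 2756 and 1903 within experiment 2, with 3876 in the same direction both ways, and an adjusted p (limma, BH) of at most 5.13e-10 for Fcgr1. The count of 4831 fell to 3208 without neutrophil replicate 3, and the higher share moved from 60.3% to 82.2% with equal library totals and 46.7% with voom weights.

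Monocytes and neutrophils, both from bone marrow and from experiment 2, were compared with each other. In monocytes S100a4 rose by 7.68 ± 0.48, Fn1 (fibronectin) by 5.77 ± 0.43, Ccr2 by 5.63 ± 0.49 and the transcription factor genes Irf8, Irf5 and Klf4 by 3.65 ± 0.42, 3.75 ± 0.33 and 3.37 ± 0.48. In neutrophils Camp stood higher, with a log2 fold change of -8.20 ± 0.94, as did Retnlg, a resistin-like protein, with -8.14 ± 0.75, Mmp9 with -7.57 ± 0.46 and Cebpe, a transcription factor of granule genes, with -5.36 ± 0.87. Of the monocyte markers, 7 rose, 2 fell and 5 did not pass (limma's camera, adjusted p = 0.00601, adjusted p = 0.104 with an estimated correlation). For neutrophil markers 0 rose, 15 fell and 3 did not pass, and 1 rose and 15 fell adjusted over the list alone (limma's camera, adjusted p = 2.10e-13, adjusted p = 0.0678 with an estimated correlation), and for the cell cycle 8 rose, 0 fell and 11 did not pass, and 10 rose and 0 fell adjusted over the list alone (limma's camera, adjusted p = 1.25e-05, adjusted p = 0.159 with an estimated correlation), with Mcm5, of the DNA replication helicase, at 2.99 and Stmn1 (stathmin) at 2.62. Of the lineage and tissue transcription factors, 8 rose, 6 fell and 20 did not pass, and 8 rose and 7 fell adjusted over the list alone (limma's camera, adjusted p = 0.842). A total of 1461 genes were higher and 1360 lower in monocytes, with an adjusted p (limma, BH) of at most 3.92e-04 for Stmn1 for the named genes. The count of 2821 fell to 1821 and 1772 without monocyte replicates 1 and 2 and to 1848 without neutrophil replicate 3, and was 1575 when only these 4 libraries were fitted, with 40.4% higher against 51.8%. The higher share was 83.1% with equal library totals and 41.5% with voom weights.

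Small and large intestine macrophages, both from experiment 1, were compared directly. Lgals2 was higher in the small intestine by 6.28 ± 0.72 and Mmp9 by 3.97 ± 0.46, as was Olfm4 (olfactomedin 4), of the small intestine epithelium, by 4.23 ± 0.69 (limma, BH, adjusted p = 0.0531 without small intestine macrophages replicate 3). Higher in the large intestine, Cyp2c55, a cytochrome P450 of the colon epithelium, had a log2 fold change of -5.56 ± 0.53 and Insl5, a peptide hormone of the colon, of -5.54 ± 0.63, and Hsd3b3, a steroid dehydrogenase, was at 36.3 ± 4.28 normalised reads in the large intestine and listed at 0 in the small intestine. Of the intestinal macrophage markers, 2 rose, 0 fell and 13 did not pass (limma's camera, adjusted p = 0.0108, adjusted p = 0.0694 with an estimated correlation), Mmp9 and Il10, which had a log2 fold change of 2.28 (limma, BH, adjusted p = 0.0706 without monocytes replicate 1, 0.0706 without monocytes replicate 2, 0.0522 without peritoneal macrophages replicate 1, 0.0527 without peritoneal macrophages replicate 2, 0.0504 without spleen red pulp macrophages replicate 1, 0.0502 without spleen red pulp macrophages replicate 2, 0.301 without large intestine macrophages replicate 2, 0.141 without large intestine macrophages replicate 3, 0.347 without small intestine macrophages replicate 3). For interferon-stimulated genes 1 rose, 0 fell and 17 did not pass, and 2 rose and 0 fell adjusted over the list alone (limma's camera, adjusted p = 9.41e-06, adjusted p = 0.0534 with an estimated correlation), the 1 being Rsad2 at 1.62 (limma, BH, adjusted p = 0.257 without large intestine macrophages replicate 3, 0.239 without small intestine macrophages replicate 3, 0.0595 without small intestine macrophages replicate 4). For inflammatory cytokines and chemokines 1 rose, 0 fell and 15 did not pass (limma's camera, adjusted p = 0.00373, adjusted p = 0.274 with an estimated correlation, adjusted p = 0.0558 without large intestine macrophages replicate 3), the 1 being Il10. For intestinal epithelium markers 1 rose, 0 fell and 9 did not pass, and 2 rose and 0 fell adjusted over the list alone (limma's camera, adjusted p = 0.864). For B cell markers 0 rose, 0 fell and 8 did not pass, and 1 rose and 0 fell adjusted over the list alone (limma's camera, adjusted p = 5.53e-04, adjusted p = 0.269 with an estimated correlation, adjusted p = 0.213 without small intestine macrophages replicate 4), and for the lineage and tissue transcription factors 0 rose, 0 fell and 34 did not pass (limma's camera, adjusted p = 0.143). In all 47 genes were higher and 90 lower in the small intestine, the named ones with an adjusted p (limma, BH) of at most 0.0435 for Il10, and every call rests on the spread between replicates of all 9 populations. With only the 4 intestinal libraries limma called 0 genes, with 1562 at an unadjusted p under 0.05 and a lowest adjusted p of 0.147, whereas voom weights over all libraries called 247. The count of 137 fell to 54 and 49 without large intestine replicates 2 and 3 and to 54 without small intestine replicate 3, and was 50 with a smaller pseudocount, 248 with a larger one, 231 with no filter, 217 with quantile normalization and 89 over genes of whole reads. With the replicate number as a block it was 2, and the calls of Lgals2, Mmp9, Olfm4, Cyp2c55, Insl5, Il10 and Rsad2 ended.

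Kupffer cells and spleen red pulp macrophages, both from experiment 2 and both users of heme iron, were compared directly. Kupffer cells were higher in Vsig4, by 6.88 ± 0.78, in Clec4f, by 6.87 ± 1.12, in Cd207, by 5.92 ± 0.70 and in C3ar1, by 4.77 ± 0.58. Spleen macrophages were higher in Slpi, an inhibitor of leukocyte proteases, with a log2 fold change of -7.56 ± 0.57, in Hs3st2 with -6.10 ± 0.61, in Itgad with -5.48 ± 0.74, in Vcam1 with -3.17 ± 0.49 and in Hmox1 with -2.50 ± 0.36. Of the Kupffer cell markers, 9 rose, 0 fell and 9 did not pass, and 10 rose and 0 fell adjusted over the list alone (limma's camera, adjusted p = 1.87e-09), and of the spleen red pulp markers 0 rose, 3 fell and 13 did not pass, and 0 rose and 7 fell adjusted over the list alone (limma's camera, adjusted p = 4.83e-06). For inflammatory cytokines and chemokines 6 rose, 0 fell and 10 did not pass, and 13 rose and 0 fell adjusted over the list alone (limma's camera, adjusted p = 1.55e-10), with the chemokine gene Ccl3 at 4.08. For interferon-stimulated genes 4 rose, 0 fell and 14 did not pass, and 5 rose and 0 fell adjusted over the list alone (limma's camera, adjusted p = 9.83e-07), with Oasl2 at 2.42 and Rtp4 at 1.91. Markers of other cells differed as well: for hepatocyte markers 8 rose, 0 fell and 0 did not pass (limma's camera, adjusted p = 1.76e-12), for endothelium markers 5 rose, 0 fell and 4 did not pass, and 7 rose and 0 fell adjusted over the list alone (limma's camera, adjusted p = 4.23e-08) and for erythroid markers 0 rose, 4 fell and 5 did not pass, and 0 rose and 5 fell adjusted over the list alone (limma's camera, adjusted p = 2.98e-06, adjusted p = 0.159 with an estimated correlation). Examples are Serpina1a, a protease inhibitor made by hepatocytes, at 5.57 and Cdh5 at 5.11. In this comparison 369 genes were higher and 366 lower in Kupffer cells, the named ones with an adjusted p (limma, BH) of at most 0.00112 for Rtp4. The count of 735 fell to 361 and 320 without spleen replicates 1 and 2. With only these 4 libraries limma called 0, with 1717 genes at an unadjusted p under 0.05 and a lowest adjusted p of 0.121, and voom weights over all libraries called 780.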

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

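Alternatives listed above as added after the data were seen were tested only then, and the others were planned. Of 473 values of the 14 counts under an alternative, 432 stayed within 1.5 times the main count. Of 6817 values of named genes under an alternative, 6746 kept their direction and their side of the threshold, 70 kept the direction and no longer passed, 0 came to pass and 1 reversed. Of 203 named gene results, 172 kept both under every alternative run. The named genes were chosen in part because their calls did not depend on the settings. These shares therefore cannot measure how stable calls are in general. Ltf in spleen against the other macrophages reversed under the subtraction, from 5.61 to -0.35; the subtraction removes signal at the level at which granule genes stood.

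The count for small against large intestine (137 genes) depended most on the processing. It was 50 with the pseudocount of 0.277, 248 with 4.43, 231 with no filter, 217 with quantile normalization, 247 with voom weights and 89 over genes of whole reads, which tests fewer genes; for the rest the cause was not tested. With the lower pseudocount 24% of its genes were higher in the small intestine, against 34.3%. With only the populations compared, which leaves 2 residual degrees of freedom for a pair of populations, the count was 0 there, 0 for Kupffer cells against spleen and 1575 for monocytes against neutrophils (main counts 735 and 2821). Limma found 1562 and 1717 genes at an unadjusted p under 0.05 in the pairs with a count of 0, where voom weights called 247 and 780. Voom weights gave 1528 genes for small intestine macrophages against 928, and the comparison within experiments gave 1275 for spleen against 2059 and 1802 restricted genes against 819, where fewer populations must be exceeded; the cause was otherwise not tested. Besides the libraries named in the results, the call of Slc1a2 in microglia ended with the larger pseudocount, no filter, quantile normalization, only the populations compared, the block, the comparison within experiments, sums of transcripts (-0.44 against -1.50) and the subtraction. That of Il10 between the intestinal populations ended with the smaller pseudocount, only the populations compared, voom weights, genes of whole reads and equal library totals, and that of Rsad2 with no mean-variance trend and only the populations compared. The estimated correlation left 59 of 168 pairs of list and comparison.

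The replicate number as a block, over the 16 numbered libraries, gave 711 genes for Kupffer cells, 1403 for lung, 117 for small intestine, 2 for small against large intestine, 419 for Kupffer cells against spleen and 338 restricted genes; the same libraries without a block moved none of the counts by over 1.5 times, and the block takes up residual degrees of freedom. The block ended the calls named for it in the results, in small intestine macrophages and between the intestinal populations, without a change of direction. Residuals of 34 pairs of libraries with the same number correlated at -0.0404 to 0.0506. The residuals of both libraries of a population mirror each other, so some of these pairs repeat others. The values show no shared shift over all genes, but they cannot tell whether libraries with the same number share an animal.

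Leaving out 1 library at a time, the count ran from 1929 to 3575 for microglia, 1348 to 2719 for peritoneal, 844 to 2192 for spleen, 837 to 1407 for Kupffer, 1146 to 2374 for lung, 340 to 1092 for small intestine and 503 to 1337 for large intestine macrophages. It ran from 904 to 2275 for macrophages against monocytes, 3208 to 4956 against neutrophils, 1772 to 2950 for monocytes against neutrophils, 49 to 173 for small against large intestine and 320 to 785 for Kupffer cells against spleen. The restricted genes ran from 617 to 822 and the list tests from 159 to 173. A comparison that loses 1 of its own 2 libraries rests on fewer samples, and the lone library is assumed to vary like the others.

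Quantile normalization shifted the median log2 fold change of all genes by 0.17 for peritoneal, -0.15 for small intestine, -0.12 for large intestine macrophages, -0.17 against monocytes and -0.23 against neutrophils. Equal library totals shifted it by 0.20 for peritoneal and -0.12 for large intestine macrophages, 0.62 for macrophages and 0.66 for monocytes against neutrophils, whose counts were then 5605 and 3575. Neutrophil libraries have the highest totals of deposited values, so directions against neutrophils are relative to the deposited scaling. Depth limits genes at few reads: the lowest library, spleen replicate 2, holds 588858 reads in genes.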

Other observations

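All tests of technical explanations in this part were chosen after the result was seen; the gene lists and their tests were planned. In lung macrophages some groups held genes that moved in opposite directions. For cholesterol efflux and LXR 1 rose, 3 fell and 8 did not pass, and 1 rose and 4 fell adjusted over the list alone (limma's camera, adjusted p = 0.449): Abcg1, a cholesterol exporter, rose by 3.47 ± 0.27 and Apoe (apolipoprotein E) had a log2 fold change of -4.27 ± 0.27. For heme and iron handling 4 rose, 5 fell and 7 did not pass, and 5 rose and 7 fell adjusted over the list alone (limma's camera, adjusted p = 0.363), with Slc11a1, a metal ion transporter of phagosomes, at -4.91 ± 0.23. For dendritic cell markers in the large intestine 1 rose, 0 fell and 4 did not pass (limma's camera, adjusted p = 0.142), the 1 being Cd209a, a C-type lectin, at 6.01 ± 0.69. For eosinophil and mast cell markers in the spleen 1 rose, 0 fell and 2 did not pass (limma's camera, adjusted p = 0.116), the 1 being Ccr3, the eotaxin receptor, at 5.98 ± 0.46 and 77.0 ± 22.2 normalised reads. These genes had an adjusted p (limma, BH) of at most 1.03e-05 for Cd209a.

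Granule genes of neutrophils were found at a low level throughout experiment 2: the median of 13 genes was 0.466% to 1.15% of the neutrophil mean in its other libraries, except Kupffer replicate 2 at 0.0922%, and 0.0103% or less in experiment 1. Expression by the macrophages was not decided. The log2 of that percent had an interquartile range over the genes of 0.582 to 1.24 (median 0.958, monocytes included). No library was over 2 and not all were under 1, the bounds of the test. That all pass was demanded after the ranges were seen. A test on genes found almost alone in a source could not tell signal crossing between pooled libraries from neutrophils among the sorted cells alone. It needed genes of all 4 other sources of experiment 2, and monocytes had 0. Crossing called for a higher percent in experiment 2 in at least 3 of these sources, and neutrophils alone called for 0. The percent was higher for 2, so neither expectation was met and the remaining values could not decide it. The median percent of these genes was higher in experiment 2 for neutrophils (0.804% against 0.153%, 40 genes higher and 7 lower). It was also higher for 2 of the other sources, spleen (0.695% against 0.418%, 4 genes higher and 1 lower) and lung (0.655% against 0.0923%, 12 genes higher and 0 lower). For Kupffer it was lower (0.646% against 0.692%, 7 genes higher and 5 lower). Monocytes had 0 such genes at a level of at least 100, and at the level of 500 first tried spleen had 0 as well, while Kupffer genes then stood at 0.801% against 0.499% (3 genes). For the sources of experiment 1 the values within it and in experiment 2 were, for microglia, 1.04% against 0.627%, 13 genes higher and 4 lower, for peritoneal macrophages 0.461% against 0.419%, 8 genes higher and 7 lower and for intestinal macrophages 1.22% against 0.778%, 8 genes higher and 5 lower; a difference between the tissues of both experiments stays open and was not tested.

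Erythroid transcripts stood high in the spleen and in Kupffer cells, with Hba-a1 (alpha globin) at 15031 and 10862 normalised reads in the spleen and 8283 and 4227 in Kupffer cells. Slc4a1 was 3.59% and 4.03% of Hba-a1 in the spleen and 0.0502% and 0.955% in Kupffer cells, a ratio of 7.58 between the means (3.99 without Kupffer replicate 1 and 75.9 without replicate 2). These 2 populations were not alone: Hba-a1 was at 17872 and 5471 in neutrophils, 3548 and 5909 in monocytes and 4092 and 1098 in microglia. As the value without Kupffer replicate 1 falls under the bound of 4 set for the test (the demand that it hold without each library was set after the value over all was seen), a single erythroid source shared by spleen and Kupffer libraries is not excluded; no biological explanation was tested. Slc4a1 was also 3.06% to 3.60% of Hba-a1 in the bone marrow cells; the cells were sorted, and the gates, which decide what erythroid cells are removed, are not given in the sources used here.

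Hepatocyte transcripts rose in Kupffer cells, 8 of 8 tested markers, with Alb at 638 normalised reads. If RNA of hepatocytes was carried into the sort in unequal amounts, the markers could differ between the replicates more than Kupffer cell markers do. Their median log2 ratio of Kupffer replicate 1 to 2 was 2.28 (range 1.05 to 3.90), against a median of 0.69 over 17 Kupffer cell markers, of which the central 90 percent lay between -0.45 and 1.75 (range -0.59 to 2.09). The hepatocyte median lay above every Kupffer marker, but the ranges overlap, so this pair of libraries cannot tell carry-over from expression or uptake. A first reference, genes restricted to Kupffer cells, held hepatocyte genes and was replaced. The demand that the ranges part was set after the median was seen outside the central 90 percent. The sort gates are not given in the sources used here.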
